A study of Homo sapiens with 4 samples.

How the data were processed

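The data came from LX-2 cells, an established human hepatic stellate cell line, in 2 untreated libraries (control) and 2 libraries treated with TGF-β1 (5 ng/ml, 24 h), grouped by their titles. Per the labels' protocols, polyadenylated RNA was selected from total RNA and libraries were made with a kit for messenger RNA. Per the submitters' processing notes, fastp 0.23.1, STAR 2.7.6a and featureCounts were used with build hg38, with no role or order stated. The caller of cytidine positions, its filters and the way the replicates of a group were combined are not given in the sources used here.

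The authors deposited 1 table per group, with a line for each position and overlapping transcript. Per the file headers, each line has a chromosome, start and end, strand, base, a column named diff, a p-value, the gene and transcript, and the segment of the transcript. The diff column holds a fraction, per the file headers and its range, with no value below 0.01. What is subtracted from what is not stated, and it is called the mismatch difference here and printed in percent. The deposited p-value of each position is below 0.05, and whether it was adjusted is not stated. Each of the 2 groups thus has 1 value per position. The tables list C as the base of every position and do not give the read base, so kinds of mismatch other than those of C were not analysed here. Depth is unknown, the planned minimum of 20 reads could not be applied, and only listed positions were used. A position absent from a table has no value, which limits every comparison of presence.

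Lines of the same position were merged, leaving 8112 control and 11735 TGF-β1 positions. Start and end differ by 1 base as in BED files, and the end is printed as the 1-based position. No genome was used here, so this reading was not checked against a C in the sequence and every printed coordinate rests on it. A position annotated to several genes (188 in control, 343 after TGF-β1) counts once among positions and once for each gene in counts per gene. Positions were shared when chromosome, base and strand were the same. Gene names were taken from the tables, and 5878 of the 6119 gene identifiers had a name found in the RefSeq gene table of assembly GRCh38.p14, which was also used for coding genes per Mb and for coding genes within 500000 bases to either side of a gene's middle. The sequence around the positions, including the CCG context, was not analysed here.

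Before the data were examined, the groups, the tests, the 20 gene lists (542 entries), the coverage minimum, the rule for named genes and a first set of alternatives were fixed. The unit of the tables needed other tests than those planned. With no reads per library, the model per position was replaced by differences with no test. Over shared positions the median difference has an order-statistic interval, with an exact two-sided sign test that treats positions as units. Shares have 95% Wilson intervals, which cover counting error only. Locations and lists were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Ratios of listed positions have 95% intervals from 2000 resamples of genes. The percentile of a list's ratio is taken among 10000 random lists of the same size matched on positions per gene, or on these and on neighbouring coding genes. These percentiles, the ratios per list and a stratified exact test that compares list members with genes of equal position number were chosen after the data were seen. Neither the random lists nor this test was matched on gene span, and the percentiles are not adjusted for the number of lists. Correlations over chromosomes used 100000 permutations.

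The named genes followed a rule with 5 parts: up to 10 shared positions with the largest difference in each direction, 1 per gene; up to 5 genes per group with a position in that list only; up to 4 members of each gene list; NAT10 and THUMPD1; and the 5 genes with most positions per group. Reads were to rank the genes of 1 list only and the list members. The largest mismatch difference and the number of listed positions over both tables were used instead, a choice made after seeing the tables. A few genes that the rule names are not reported here. Other genes given as examples within a list were chosen after their values were seen.

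The statistics were tested on simulated data. A shift of 1.5 points planted at 1985 shared positions was estimated at a median of 1.51, with 93% of the 95% intervals covering it. A 200-gene list planted with a 3-fold excess was called in 96% of sets or more by the stratified test. The lists tested here had at most 60 listed genes, so this rate does not hold for them, and their power was not simulated. With no list effect the stratified test made a call in 1% of 100 simulated sets and Fisher's test in 72%. There each position fell to a group at random, without the differences between genes and gene classes seen in the 2 lists. The rate of false calls with such differences was not simulated. Alternatives were a minimum of 10%, removal of positions of 90% or more, exonic positions only, wider definitions of sharing and, added after the data were seen, an authors' p below 0.001, removal of p-values of exactly 0, removal of noncoding exons and positions of several genes, a TGF-β1 list shortened to the control's length, and removal of chromosome 19 or of shared positions. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.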

Results

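LX-2 is an established human hepatic stellate cell line, the cell type that turns into the collagen-producing myofibroblast of the fibrotic liver. TGF-β1 is the growth factor most often used to drive that activation in culture. The study asked how N4-acetylcytidine (ac4C), an acetylated form of cytidine in RNA that NAT10 writes, differs between untreated cells and cells given TGF-β1 at 5 ng/ml for 24 h. Polyadenylated RNA was treated with sodium borohydride (NaBH4), which reduces ac4C to a form that reverse transcriptase can misread, so that the base is recorded as T. The 4 libraries were 2 untreated and 2 treated with TGF-β1, described as biological replicates. None of them is labelled as made without NaBH4 or with NAT10 depleted. A listed position is thus a C mismatch that was not shown here to be ac4C. The deposited data were 1 table of cytidine positions per group. Each position carried 1 mismatch difference, given here as a percentage, and 1 p-value of the authors. Every position was listed with C as its base, taken here as that of the transcript strand, which was not checked. The tables give no reads, depths or values per library, so no value has a replicate error and no interval for a single position can be given. Intervals and tests over positions or genes describe the 2 lists and do not measure the spread between cultures. The difference between the groups has no replicate check.

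After TGF-β1 more cytidines were listed than in untreated cells, and most of them were other cytidines. The control table held 8112 positions in 4384 genes and that of TGF-β1 held 11735 positions in 4444 genes, a ratio of 1.45. With a position counted for each gene it lies in, the ratio was 1.46 (95% interval 1.41 to 1.502 when genes were resampled). Genes with several positions were more frequent: 1580 genes (35.6%) had 3 or more positions after TGF-β1, against 891 (20.3%) in control. That count moves with the length of the list: with the TGF-β1 list shortened to the control's length by lowest p, 1047 genes had 3 or more. Both lists held 1985 positions, which was 24.5% of the control list (95% Wilson interval 23.5 to 25.4) and 16.9% of the TGF-β1 list (16.2 to 17.6). Genes overlapped more than positions did, with 2716 of the 6112 genes in both tables. Within those genes 34.5% of the control positions recurred. Over all genes, 3127 had more listed positions after TGF-β1, 2155 had fewer and 830 had equal numbers. A mismatch difference of at least 10% was listed at 1009 control and 2169 TGF-β1 positions, a ratio of 2.17 with a position counted for each gene, and 147 such positions were listed in both groups. At a matched mismatch difference of 5 to 10%, the median p-value of the authors was 0.000105 in control and 3.14e-06 after TGF-β1, and it was lower after TGF-β1 in all 6 ranges of mismatch difference compared. Depth is unknown, so whether more reads after TGF-β1 lengthened its list could not be tested.

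At the 1985 cytidines listed in both groups, the mismatch difference was higher after TGF-β1 at 1556 (78.4%, 95% Wilson interval 76.5 to 80.1). The median was 3.78% in control and 5.77% after TGF-β1. The median of the paired differences was 1.73 percentage points (95% interval 1.57 to 1.91), and the median log2 ratio was 0.58 (0.54 to 0.63). The exact two-sided sign test gave p = 1.57e-149 with positions, not cultures, as units. Positions in 5'UTRs had a median difference of 1.45 points, those in coding sequence 1.77 and those in 3'UTRs 1.99. The 27 shared positions in noncoding exons had a median difference of 0.50 points (exact sign test p = 0.442). A difference of at least 10 points upward was present at 138 positions, and 1 of that size downward at 2.

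**Figure D1:**
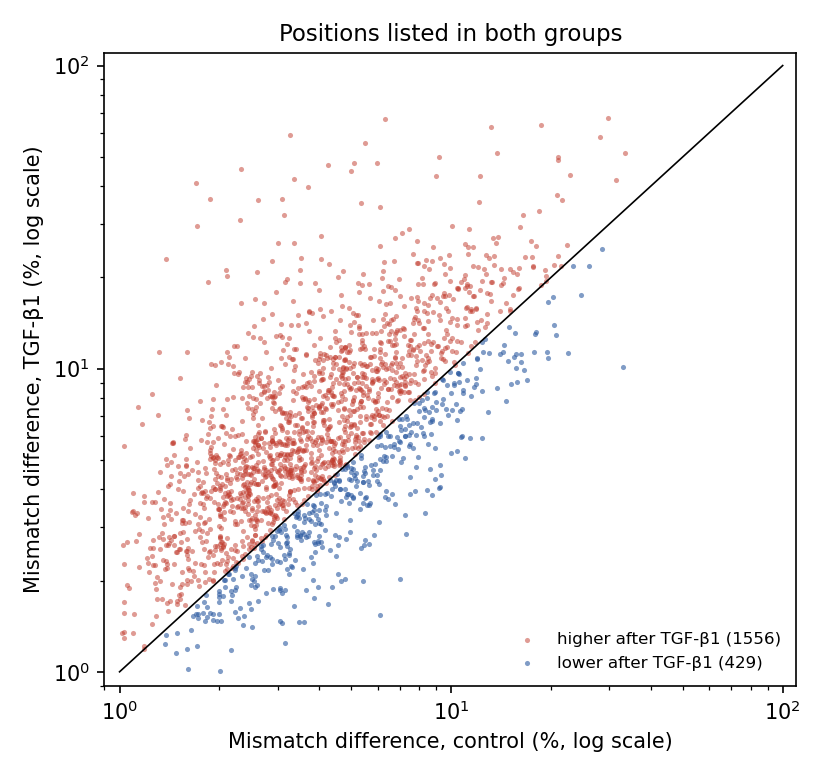
Mismatch difference (%) of each of the 1985 cytidines listed in both groups, control on the x axis and TGF-β1 on the y axis, both on log scales, with the line of equal values. The 1556 red points above the line are higher after TGF-β1 and the 429 blue points are not.

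The position with the largest upward difference was in the coding sequence of SLMAP (ENSG00000163681), a tail-anchored membrane protein first found in the sarcolemma, at chromosome 3 position 57862035 on the plus strand of hg38, with 6.30% in control and 66.7% after TGF-β1. Coordinates here assume that the tables count from 0 as BED files do, which was not checked against the sequence. NIPBL, the cohesin loader, had 3.28% and 59.1% at chromosome 5 position 37048536. DAB2, an endocytic adaptor that binds TGF-β receptors, had 5.498% and 55.7% at chromosome 5 position 39390462. MFN1, a GTPase of mitochondrial outer membrane fusion, had 13.2% and 62.5%, and OSBPL9, an oxysterol-binding family member, 18.7% and 63.7%. SMARCA2, an ATPase of the SWI/SNF chromatin remodeller, had 2.33% and 45.7%, and GOLGA4, a golgin, had 5.995% and 47.8%. EIF4G2, a translation initiation factor homologous to EIF4G1, had 4.25% and 47.0% at chromosome 11 position 10801081. The remaining position of this kind had 9.19% and 50% and is annotated both to ANKHD1 and to its readthrough transcript with EIF4EBP3. All of these positions lay in coding sequence, and none has a replicate value. Most of these genes had fewer listed positions after TGF-β1, with 3 and 1 in SLMAP, NIPBL and GOLGA4, 2 and 1 in DAB2, MFN1 and OSBPL9, 6 and 3 in SMARCA2 and 5 and 2 in ANKHD1, while EIF4G2 had 6 and 10. Over all shared positions the median log2 ratio was 0.85 in genes with fewer positions after TGF-β1 and 0.50 in genes with more. At the positions in MFN1 and ANKHD1 the authors' p-value after TGF-β1 was exactly 0.

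Downward differences were smaller. TUBA4A (ENSG00000127824), an alpha-tubulin, had 33.0% in control and 10.1% after TGF-β1 at chromosome 2 position 219250442 on the minus strand, in coding sequence. RRAS, a small GTPase of the Ras family, had 22.5% and 11.3% at chromosome 19 position 49640078. The differences in DYNLT2B, LRRC42, RGL2, SURF6, LAYN, TCF3 and GFER ran from -8.85 to -6.80 points. LAYN, a hyaluronan receptor, had 24.6% and 17.5%, and TCF3, an E-protein transcription factor, had 15.8% and 9.01%. The DYNLT2B position is also annotated to ENSG00000272741. The positions in RGL2, SURF6 and GFER lay in 3'UTRs. The authors' p-value was exactly 0 after TGF-β1 in RGL2 and in both groups in GFER.

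Some of the highest mismatch differences stood in 1 list alone. In the control list these were a 3'UTR position of RERE, a nuclear receptor corepressor, at 83.3% (chromosome 1 position 8355070), a noncoding exon of the pseudogene MYL12BP1 at 70.8%, and 5'UTR positions of AP1AR at 64.9%, UCHL1 at 58.9% and B2M, the light chain of MHC class I, at 55.6%. In the TGF-β1 list they were a 5'UTR position of CBX3, a heterochromatin protein, at 100% (chromosome 7 position 26201549), a noncoding exon of the pseudogene RPL23AP74 at 74.98%, a coding position of the actinin gene ACTN2 at 68.6%, a 5'UTR position of CCAR2 at 66.7% and a coding position of EPS15 at 63.2%. The authors' p-value was exactly 0 at the positions in MYL12BP1, CBX3, ACTN2 and CCAR2. Positions with a p-value of exactly 0 seldom recurred, with 5.52% of 652 in control and 4.33% of 1293 after TGF-β1 found in the other list, against 26.1% and 18.5% of the other positions. Reads of the 2 pseudogenes can come from near-identical parent genes. A position missing from a list can be unmodified, below the authors' threshold or uncovered. Among control positions of 20% or more, 11.3% were listed again after TGF-β1, against 27.5% of those from 2 to 3%.

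Large cytoskeletal genes were among those with most listed positions after TGF-β1. PLEC, the cytolinker plectin, had 26 positions in control and 74 after TGF-β1, and 14 of its 16 shared positions were higher after TGF-β1. The actin crosslinkers FLNC and FLNA had 16 and 47 and 11 and 33 positions, and MYH9, a nonmuscle myosin heavy chain, had 13 and 35. In the control list PLEC also led, followed by NUMA1 with 18 positions against 15 after TGF-β1, TRIO with 18 against 5, AHNAK with 17 against 4, and FLNC. Further genes were picked after their values were seen. KIF1C, a kinesin, had 2 positions in control and 21 after TGF-β1, CAVIN1, a caveolar coat protein, 2 and 17, and PHLDB1 2 and 17. In the other direction DYNC1H1, the dynein heavy chain, had 16 and 2, MYLK, the myosin light chain kinase, 11 and 0, RNF213 11 and 0, UBR4 9 and 0, and DNMT1, the maintenance DNA methyltransferase, 9 and 1. NAT10, the ac4C writer, had 2 coding positions in control and 1 after TGF-β1. The shared NAT10 position, chromosome 11 position 34141811, had 1.46% and 2.26%. THUMPD1, the tRNA adaptor of NAT10, had 1 coding position in control at 5.70% and 0 after TGF-β1.

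Genes of stellate cell activation and contraction carried more listed positions after TGF-β1. Of the 33 listed members, 29 had more and 2 had fewer, and their positions numbered 121 in control and 313 after TGF-β1, a ratio of 2.59 (95% interval 2.03 to 3.18, genes resampled). That ratio stood at the 99.5th percentile of 10000 random lists matched on positions per gene, whose median was 1.80. Percentiles here and below are not adjusted for the number of lists, and gene span was not matched. ACTA2, the smooth muscle actin that marks activated stellate cells, had 0 positions in control and 2 after TGF-β1, at 7.80% and 5.41%. TAGLN, an actin-binding protein of contractile cells, had 2 and 9 positions, TPM2 0 and 9, ACTN4 0 and 13, MYL9 1 and 11, and ITGA5, the fibronectin receptor subunit, 3 and 15. MYH10 with 8 and 2 positions and VCL with 6 and 1 were the members with fewer. At the 55 shared positions of this list 37 were higher after TGF-β1 (adjusted p = 0.0867, exact sign test against equal numbers). Of all shared positions 78.4% were higher, and the difference between the list and all positions was not tested. Depth and transcript level are not given. More listed positions, here and in the lists below, can also come from more reads of a transcript.

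Enzymes that process and crosslink matrix and the list of collagens and other matrix proteins both carried more listed positions after TGF-β1, and their ratios, whose intervals overlap, were not tested against each other. Of 23 listed matrix remodelling genes, 18 had more positions after TGF-β1 and 1, the protease ADAMTS1, had fewer, with 44 positions in control and 113 after TGF-β1 (ratio 2.57, 1.85 to 3.76, 98.2nd percentile, random median 1.73). TGM2, a matrix-crosslinking transglutaminase, had 1 and 15 positions, LOXL2, a lysyl oxidase, 4 and 9, the protease CTSB 2 and 10, and P4HB, a subunit of the collagen prolyl hydroxylase, 5 and 7. Of 30 collagen and other matrix protein genes, 18 had more and 11 had fewer, with 114 and 187 positions (ratio 1.64, 1.25 to 2.04, 28.5th percentile, random median 1.81). COL4A2 had 9 and 26 positions, COL6A2 4 and 18, COL5A1 8 and 16, and FN1, fibronectin, 8 and 16. COL1A1 had 4 and 10 positions, with 2 in both lists, 1 higher and 1 lower after TGF-β1. FBN2 with 5 and 0 and COL12A1 with 3 and 0 went the other way.

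Genes of TGF-β and SMAD signalling were divided. Of 19 listed members 8 had more positions after TGF-β1 and 10 had fewer (28 and 52 positions, ratio 1.86, 0.905 to 2.91, 70.6th percentile). TGFBI, a TGF-β-induced matrix protein, had 4 and 13 positions, TGFB1 itself 4 and 9, and PMEPA1, a feedback inhibitor, 0 and 6. The receptor genes TGFBR1 with 1 and TGFBR2 with 2 positions, and SMAD2 with 2, were in the control list only.

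Transcripts of the translation machinery and of mitochondria also had more listed positions after TGF-β1. Ribosomal protein genes had 50 positions in control and 141 after TGF-β1 (ratio 2.82, 2.11 to 3.88), at the 100th percentile of the random lists (median 1.41), with 45 of 60 listed genes having more and 4 fewer. The shortest of 4 classes of genes by span had a ratio of 2.07, and the random lists were not matched on span. RPS3 had 2 and 7 positions, RPL13 1 and 7, RPL35 1 and 6, and RPL7A 3 and 5. At their 28 shared positions 22 were higher after TGF-β1 (adjusted p = 0.0335, exact sign test against equal numbers, over 18 lists). Of all shared positions 78.4% were higher, and the list's median log2 ratio of 0.39 (0.16 to 0.75) has an interval that holds the 0.58 of all. Translation factors had 56 and 130 positions (ratio 2.32, 1.80 to 3.03, 96.1st percentile, random median 1.68), and 23 of 25 shared positions were higher (adjusted p = 0.00035, same exact sign test). Their median log2 ratio of 0.65 (0.25 to 1.18) has an interval that holds 0.58 too. EIF4G1, the initiation scaffold, had 8 and 18 positions, all 4 shared ones higher, and EEF2 and EIF3A each had 4 and 9. EIF4G2 had 6 and 10, and its 5 shared positions were all higher, by a median of 33.5 points. The sign test counts the shared positions of EIF4G1 and EIF4G2 as independent, which positions of 1 gene may not be. Of 18 nuclear genes of oxidative phosphorylation 13 had more and none fewer, with 17 and 54 positions (ratio 3.18, 1.999 to 6.67, 99.4th percentile, random median 1.54). SDHA, the flavoprotein of succinate dehydrogenase, had 1 and 10 positions, and ATP5F1B, an ATP synthase subunit, 4 and 8. Of 8 mitochondrially encoded genes 6 had more, with 3 positions in control and 16 after TGF-β1, among them MT-CYB with 0 and 4 and MT-CO1 with 0 and 3. Glycolytic genes had 40 and 94 positions (ratio 2.35, 1.69 to 3.34, 93.4th percentile), with 15 of 21 genes having more, such as PKM with 2 and 11 and ENO2 with 1 and 9. The interval of the glycolytic genes holds 1.72, the median of their random lists.

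For several gene groups the interval of the ratio held that of all genes, 1.46. Members of the Hippo and YAP pathway had 24 positions in control and 20 after TGF-β1 (ratio 0.833, 0.312 to 1.91, 3.64th percentile). Among them the angiomotin family genes AMOTL1 and AMOTL2 had 6 and 0 and 5 and 2 positions, while the receptor kinase AXL had 2 and 8. Lipid and retinoid genes had 15 and 15. RNA editing and modification enzymes had 23 and 26 (ratio 1.13, 0.450 to 2), with ADAR, the adenosine deaminase, at 4 and 0 and the RNA-binding protein YBX1 at 3 and 7. Genes of RNA acetylation and ribosome assembly had 18 and 29 (ratio 1.61, 0.800 to 3.002), including the nucleolar methyltransferase FBL with 0 and 7 and nucleolin, NCL, with 4 and 8. Secretory pathway and unfolded protein response genes had 41 and 66 (ratio 1.61, 1.07 to 2.29), with the chaperone CALR at 2 and 11. Cell cycle genes had 44 and 76 (ratio 1.73, 1.00 to 2.82), among which the replicative helicase subunits MCM2 and MCM3 each had 2 and 8 and the proliferation marker MKI67 had 9 and 0. Transcripts known as targets of ADAR or APOBEC enzymes had 30 and 65 positions (ratio 2.17, 0.571 to 3.14), of which FLNA had 11 and 33. Markers of other liver cell types were scarce. None of the hepatocyte markers was listed, CD68 was the 1 macrophage marker with 3 and 2 positions, the endothelial markers TIE1 and FLT1 had 6 positions in each list together, and 3 cholangiocyte markers had 2 and 6, of which KRT18 had 0 and 5.

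**Figure D2:**
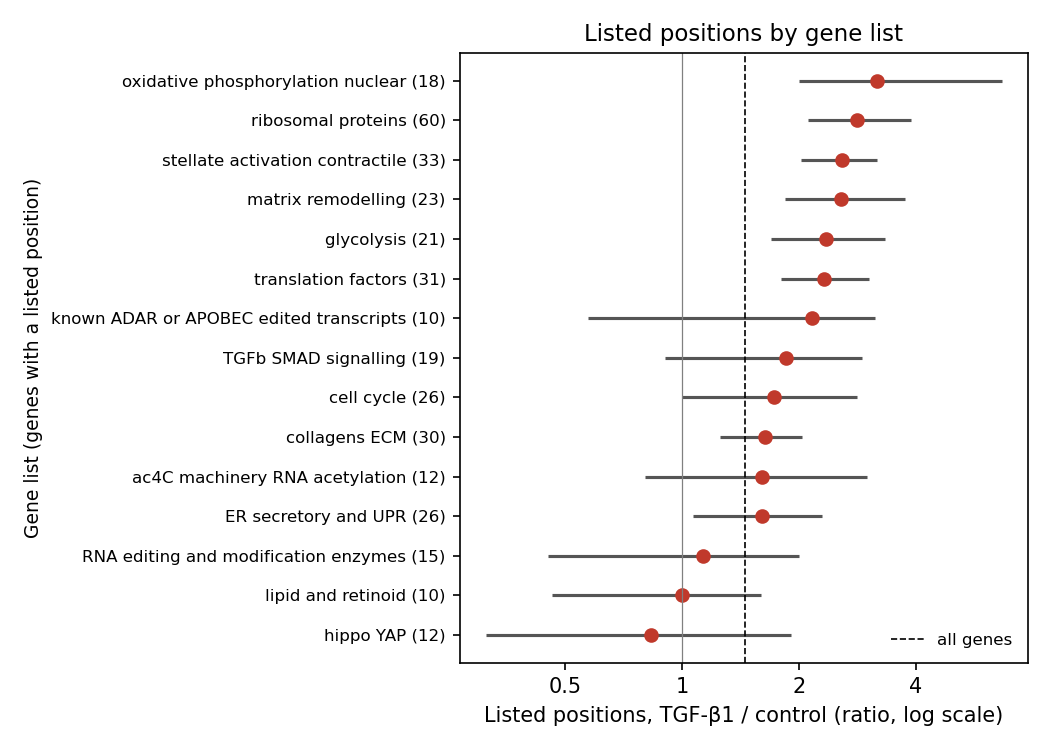
Ratio of listed positions, TGF-β1 over control, on a log x axis for the gene lists with at least 10 listed genes (number of genes in brackets), with 95% intervals from resampling genes. The intervals are not adjusted for the number of lists. The dashed line is the ratio of all genes, 1.46, and the oxidative phosphorylation, ribosomal, contractile, matrix remodelling and translation factor lists have intervals wholly to its right and above the median of their matched random lists, while that of glycolysis lies to its right but holds its random median of 1.72.

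Fisher's exact test (two-sided, Benjamini-Hochberg over 38 tests) asked whether the members of a list were found in 1 table only more or less often than other genes. It gave 5 calls. By this exact test, none of the 33 contractile genes (adjusted p = 0.000746), none of the 23 matrix remodelling genes (adjusted p = 0.0131) and none of the 18 oxidative phosphorylation genes (adjusted p = 0.0445) was in the control table only, against 27.4% of other genes for each list. Of 60 ribosomal protein genes 3 were (adjusted p = 0.000553, Fisher's exact test). The matrix protein list had 1 of 30 genes, COL3A1, in the TGF-β1 table only, against 28.4% of other genes (adjusted p = 0.0109, Fisher's exact test). Genes with many positions are seldom in 1 table only, and in simulated tables with no list effect the test made at least 1 call in 72% of sets. When genes were compared with others of equal position number by a stratified exact test, the ribosomal protein genes kept their call (5.00% against 22.4% expected in the control table only, adjusted p = 0.0031) and gained 1 for the TGF-β1 table only (43.3% against 25.2%, adjusted p = 0.0237). The others did not pass the stratified exact test (adjusted p = 0.65 for the contractile, 0.667 for the matrix remodelling, 0.0539 for the oxidative phosphorylation and 0.188 for the matrix protein list). Among positions of at least 10%, Fisher's exact test gave 0 calls, and the ribosomal difference from other genes turned to 5.30 points for the control table only (adjusted p = 0.952) and to -5.01 for the TGF-β1 table only. The oxidative phosphorylation call was also lost at an authors' p below 0.001, and the matrix protein call without p-values of 0. The differences from other genes were then -25.5 and -20.5 points, against -27.4 and -25.1 with all positions.

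Listed cytidines lay mostly in coding sequence in both groups. Coding positions made up 74.7% of the control list (95% Wilson interval 73.7 to 75.6) and 76.3% of the TGF-β1 list (75.6 to 77.1), which differed by Fisher's exact test (adjusted p = 0.0206 over 5 locations). Noncoding exons held 2.71% (2.38 to 3.09) in control and 1.63% (1.41 to 1.87) after TGF-β1 (adjusted p = 1.01e-06, Fisher's exact test). The 5'UTR shares were 9.87% and 9.96% (adjusted p = 0.847) and the 3'UTR shares 12.6% and 11.99% (adjusted p = 0.276, same exact test). Introns held 5 and 9 positions. The difference in coding share was lost without noncoding exons and positions of several genes (0.824 points, adjusted p = 0.465, exact test) and at an authors' p below 0.001 (1.31 points, adjusted p = 0.248, exact test). In the other alternatives run for location the coding difference passed the threshold. Among positions of at least 10% it was 8.44 points (adjusted p = 1.15e-05, exact test). There the 3'UTR share was lower after TGF-β1 (difference -4.91 points, adjusted p = 0.00132, exact test). The 3'UTR difference was -1.26 points and past the threshold both with the TGF-β1 list shortened to the control's length and without shared positions.

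The ratio of listed positions differed between chromosomes. Among the nuclear chromosomes the ratio was highest on chromosome 19, with 608 positions in control and 1368 after TGF-β1, a ratio of 2.25 (95% interval 2.04 to 2.51, genes resampled). Chromosomes 22 and 17 followed with 1.75 and 1.66. The mitochondrial genome, with 3 and 16 positions, had a ratio of 5.33. The lowest ratios were 0.929 on chromosome 18, 1.01 on chromosome 4 and 1.01 on chromosome 15. Over 23 chromosomes the ratio went with the number of protein-coding genes per Mb (Pearson's r = 0.859, permutation p = 2e-05, the smallest the permutations can give; Spearman's coefficient = 0.757, permutation p = 4e-05; adjusted p = 4e-05 for both). Without chromosomes 17 and 19, Pearson's r was 0.747 and Spearman's coefficient 0.684. Chromosomes are not independent replicates. Among single genes split into 4 classes by coding neighbours within 500000 bases to either side, the class with fewest had a ratio of 0.898 (0.830 to 0.967) and the class with most had 2.03 (1.92 to 2.15). Split into 4 classes by genomic span, the shortest genes had a ratio of 2.07 (1.95 to 2.20) and the longest 0.818 (0.753 to 0.883). Neighbours and span each went with the ratio when genes were divided at the median of both. With more neighbours it was 2.15 (2.05 to 2.26) for shorter and 1.43 (1.31 to 1.54) for longer genes, and with fewer it was 1.60 (1.48 to 1.73) and 0.928 (0.866 to 0.994). Among random lists matched on neighbours as well, the ratio stood at the 99.6th percentile for the contractile genes, the 99.1st for matrix remodelling and the 99.2nd for oxidative phosphorylation. That of the matrix protein list moved from the 28.5th to the 58.4th percentile. Counted by gene, the ratio among positions of at least 10% was 2.17 for all genes, 1.44 for the class with fewest neighbours and 2.94 for that with most, and 1.36 for the longest and 2.73 for the shortest genes. At an authors' p below 0.001 it was 1.77 for all genes, and 1.10 and 2.43 for the classes with fewest and most neighbours. The ratio of the lower class thus passed 1 while the order of the classes stayed.

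**Figure D3:**
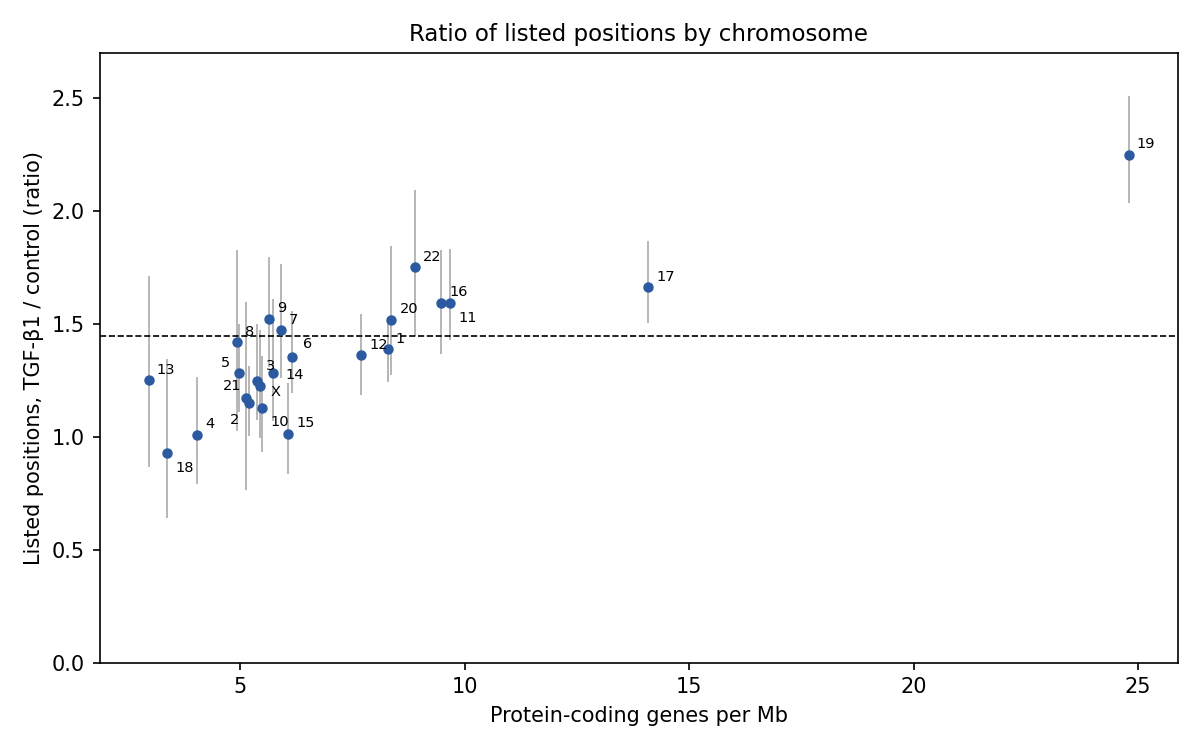
Ratio of listed positions, TGF-β1 over control, of each chromosome (number beside the point) against its protein-coding genes per Mb, with 95% intervals from resampling genes and the overall ratio of 1.45 as a dashed line. Chromosome 19 lies at 2.25 and chromosome 18 at 0.929.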

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

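The alternatives with an authors' p below 0.001, without p-values of 0, without noncoding exons and positions of several genes, with a shortened TGF-β1 list, without chromosome 19, without shared positions and with genes matched on position number were chosen after the results were seen. The higher mismatch difference at shared positions kept its direction and passed the sign test under every alternative run, and the share in noncoding exons stayed lower after TGF-β1 in each that kept them. The alternatives reuse the same positions and values, so they are no independent check. Shortening the TGF-β1 list by lowest p favours a higher value after TGF-β1, since the median p fell as the mismatch difference rose. The median difference at shared positions was 4.04 points with a minimum of 10% and 1.68 to 2.10 in the other alternatives. With a minimum of 10%, 147 positions and 304 genes were in both lists, 14.6% of control positions recurred and the ratio of listed positions, here and below counted for each gene, was 2.17. There Fisher's tests gave 0 calls, with differences of -20.5 points for matrix proteins, -18.4 for matrix remodelling, -26.0 for oxidative phosphorylation and -9.39 for contractile genes, while ribosomal genes turned to 5.30 for the control table only and -5.01 for the TGF-β1 table only. Fewer positions were left to test. The coding difference was then 8.44 points and the 3'UTR difference -4.91, both past the threshold, and the 5'UTR difference turned to -0.466. As the ratio of all genes rose, those of the longest genes and of genes with fewest coding neighbours passed 1, at 1.36 and 1.44. The shortest genes had 2.73 and those with most neighbours 2.94. With an authors' p below 0.001, 1092 positions and 1726 genes were shared, the ratio was 1.77, the 3'UTR difference turned to 0.0339 and the 5'UTR difference to -0.464, the coding difference of 1.31 and the oxidative phosphorylation difference of -25.5 were no longer past the threshold, and the ratio of genes with fewest neighbours was 1.10 beside 2.43 for those with most. Without p-values of 0 the ratio was 1.41, 25.6% recurred, and the matrix protein difference of -20.5 was not past the threshold. Without noncoding exons and positions of several genes the coding difference was 0.824 and the 5'UTR difference -0.0176. With the TGF-β1 list shortened to the control's length by lowest p, the ratio was 1.00 by construction, 18.8% recurred and the 3'UTR difference was -1.26, past the threshold. Without chromosome 19 the ratio was 1.39 and the 5'UTR difference -0.0844. Without shared positions the ratio was 1.60 and the 3'UTR difference -1.26, past the threshold. The ratios of the ribosomal, matrix remodelling and contractile lists were then 5.14, 4.14 and 3.91. With the shortened TGF-β1 list they were 2.58, 2 and 2.14. Taking the same positions out of both lists raises any ratio above 1 by construction. The higher ratios without shared positions therefore do not show a stronger difference. Matched on position number, 2 list tests passed, and matrix proteins had -11.6 points, matrix remodelling -6.25, oxidative phosphorylation -23.8 and contractile genes -5.60, none past the threshold. Counted by gene, 5750 control positions lay in a gene of the TGF-β1 list. The cause of the changes that are not fixed by construction was not tested. No paired analysis was possible because the tables carry 1 value per group, although the labels number the replicates alike. Coverage minimums of 10 and 50 reads, leaving out a replicate, the models per position and their minimum differences, known variants, the strand alternative, a background of other changes and all settings for sequence context were not run. Depth is unknown and limits what absence from a list shows.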

Other observations

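For sequencing depth alone, uneven coverage and numerical underflow, the predictions were written only after the results they concern were seen. Several transcripts had more than 1 cytidine with a large difference. In SMARCA2, the SWI/SNF ATPase, the 3 shared coding positions at 2161774, 2186113 and 2186140 of chromosome 9 had 1.70%, 2.33% and 3.35% in control and 40.9%, 45.7% and 42.1% after TGF-β1, while its listed positions numbered 6 and 3. In EIF4G2, all 5 shared coding positions had 2.09 to 5.11% in control and 21.1 to 47.6% after TGF-β1. Recurrence went opposite ways in the 2 lists: it was 25.8% (95% Wilson interval 23.3 to 28.5) below 2% and 11.3% (7.61 to 16.6) at 20% and above in control, and 9.08% (7.57 to 10.9) and 22.2% (18.8 to 26.0) in the TGF-β1 list.

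At the cytidines in both lists the mismatch difference was higher after TGF-β1 by a median of 1.73 points (95% interval 1.57 to 1.91). Deeper TGF-β1 libraries alone were predicted to leave no such excess, since the shallower control list would keep its highest values. That prediction was written after the excess was seen and was set against the excess itself, and depth is unknown. It is therefore no separate test, and depth stays open. A shift of conversion or background common to all transcripts is argued against as the whole cause, because the class of genes with fewest coding neighbours had a median log2 ratio of 0.87 (0.72 to 0.92), 0.28 above that of all positions, but the other classes had 0.56, 0.55 and 0.47, so such a shift together with uneven coverage stays open. Genes of the matrix, activation and TGF-β lists did not have the higher log2 ratio predicted of them. Their difference from other genes was -0.18 (-0.35 to 0.03), an interval that includes no difference. They held only 134 of the 1985 shared positions, so they could hardly have carried the excess whatever their ratio. Uneven coverage, with fewer reads after TGF-β1 in genes that lost positions, could contribute, because the log2 ratio was higher by 0.34 (0.20 to 0.46) in genes with fewer positions after TGF-β1 than in genes with more. A change in acetylation spread over many transcripts stays open and was not tested.

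Among the nuclear chromosomes the ratio of listed positions was highest on chromosome 19. Without the genes of the matrix, activation and TGF-β lists, which are 5 of its 480 listed genes, it was 2.23 (2.02 to 2.47). These genes therefore do not carry the gain, but removing so few could hardly have moved the ratio. A bias that follows gene density may be involved, since off chromosome 19 and among genes of no list the ratio in the densest of 4 classes was 2.28 times (2.05 to 2.53) that in the sparsest. Dense genes are often short, but with genes divided at the median span the denser ones had the higher ratio among the shorter (2.15 against 1.60) and the longer (1.43 against 0.928), where shorter genes also had the higher ratio at either density. Gene length therefore stays open beside density, and within chromosome 19 the ratio was 1.16 times as high in the shorter genes as in the longer (0.95 to 1.42), an interval that holds 1. A response to TGF-β1 in transcripts of gene-dense regions also stays open and was not tested.

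A p-value of exactly 0 stood at 652 control and 1293 TGF-β1 positions, of which 5.52% and 4.33% recurred in the other list, against 26.1% and 18.5% of the other positions. Numerical underflow of very small p-values is argued against, because only 86 p-values above 0 were below 1e-100 beside 1945 at 0. Few reads may lie behind them, as 34.1% were in genes with a single listed position against 19.9% of the others, a difference of 14.3 points (12.1 to 16.4). They lay in 3'UTRs more often than the others did, at 25.9% against 11.5% in control and 24.4% against 10.5% after TGF-β1. No biological explanation was tested.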
